A study of Mus musculus with 12 samples.

How the data were processed

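Bone marrow was taken from the hind legs of male C57BL/6 mice aged 10 to 12 weeks, and cells carrying CD71, the transferrin receptor that is abundant on red cell precursors, were enriched with a biotinylated antibody and magnetic beads. Total RNA from each mouse was labelled with biotin and hybridised to a whole-transcript Affymetrix array, a 1-colour array that measures each transcript with a set of probes. The series holds 12 arrays in 4 groups of 3 mice. The groups are wild type (WT), mice with a CD70 transgene (CD70TG), mice lacking the gene for interferon-gamma (Ifng-/-) and transgenic mice lacking it (CD70TG*Ifng-/-). The labels number separate mice, so each array is a separate animal. Groups were taken from the labels, and all 12 arrays were used.

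The deposited values are on a log2 scale and were made by the authors with RMA, a method that corrects background, equalises the arrays and combines the probes of a probe set, per the submitters' processing notes. Its version and the annotation it ran with are not given in the sources used here. In the deposited log2 table the median of every one of the 28815 probe sets over the 12 arrays was 0 within 0.000001, so each value is relative to that probe set's own median and absolute levels are not held. The lowest value was -3.25 and the highest 6.70. The medians of the arrays were 0.001, -0.006 and 0.007 in WT, -0.012, -0.007 and 0.007 in CD70TG, -0.021, -0.005 and 0.001 in Ifng-/-, and 0.002, 0.027 and 0.008 in CD70TG*Ifng-/-. The log base and the direction (higher for more RNA) were taken from what RMA gives and are stated by no label or header, and how and why the probe sets were centred is unknown.

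Some information on level could be recovered from the rounding of the deposited numbers. Values stored in single precision before centring keep a step that depends on the power of 2 they lie under, and this step placed 4358 probe sets (15.1%) at an original log2 level of at least 8 and 24457 at 4 to 8, with a tolerance of 0.05 of a step and values under 0.001 left out. As a check, 47 of 67 ribosomal protein genes and 1 of 1027 olfactory receptor genes fell in the higher class. Signal over background cannot be given beyond these level classes, and for arrays only their number limits the precision that can be stated.

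Probe sets were named from the platform annotation that GEO holds, which can be old: 21780 had 1 gene symbol, 1605 had several and 5430 had none in the table used. Of the first, 21689 were matched by Entrez identifier to a table of mouse genes with no assembly named, which changed 0 symbols and was otherwise used only for chromosomes and neighbourhood. Probe sets with several symbols or none named no gene. Genes measured only by such probe sets are not analysed here. The design fixed before the data were examined took, for a gene with several probe sets, the one with the highest mean. Centred values do not hold that mean, so the average of a gene's probe sets was used, which applied to 998 of 19935 genes. For the same reason both planned filters on the dimmest genes could not be run, and no gene was removed.

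A linear model with 4 group means was fitted to the 12 arrays with limma 3.58.1 (lmFit and eBayes, 8 residual and 6.20 prior degrees of freedom) in R 4.3.3 with statmod 1.5.0. From it came the transgene effect with Ifng intact (CD70TG against WT) and without Ifng (CD70TG*Ifng-/- against Ifng-/-), the effect of Ifng loss without the transgene (Ifng-/- against WT) and with it (CD70TG*Ifng-/- against CD70TG), and the interaction, which is the first transgene effect minus the second. All limma tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over 19935 genes, and the threshold was 0.05. All adjusted p-values of genes are limma's. Fixed before the data were examined were 29 gene lists, 28 of which had at least 5 measured members and were tested with limma's camera, a test of a list against all other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. The list of sex-linked genes had 4 measured members and was not tested. Camera with a correlation estimated from the arrays and limma's fry, a test of whether a list's genes move on balance in a given direction, were alternatives. Counts adjusted over the list alone use only the p-values of a list's members.

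The genes named were set by a rule before the data were examined. It takes Cd70, Cd27, Ifng, Irf1, Socs1, Spi1, Gata1, Klf1, Epor and Tfrc always, then for CD70TG against WT the 10 higher and 10 lower genes with the largest change past the threshold and no overlap between the groups. For each other contrast it takes 5 and 5 by the same rule, with no condition on overlap for the interaction. It then takes up to 4 members of each list with the smallest p. Genes without an official symbol were skipped.

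The test was tried on simulated data of 19935 genes with the spread of these arrays and 200 changed genes. For CD70TG against WT it recovered 77.6% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2, with 5.07% false calls. For CD70TG*Ifng-/- against Ifng-/- these shares were 73.1%, 98.5% and 98.5%, with 6.16% false calls. For Ifng-/- against WT they were 88.1%, 98.5% and 100%, with 6.33% false calls. For CD70TG*Ifng-/- against CD70TG they were 71.6%, 100% and 100%, with 3.37% false calls. For the interaction they were 43.3%, 91.0% and 98.5%, with 4.12% false calls. In each of these comparisons a simulated list of 25 genes shifted by 0.5 was found by camera, by camera with an estimated correlation and by fry, and 0 of 20 unchanged lists were called. The simulated genes varied independently of each other, so this does not try the list tests on lists whose genes move together.

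Alternatives planned before the data were examined were quantile normalization, median centring of each array, a fit of only the groups compared, the replicate number as a block, every probe set in place of genes, eBayes with a trend and robust prior, array weights, a stricter threshold of 0.01 or of at least a 2-fold change, the other list tests, and leaving out each array in turn. The trend carries no intensity here, since the values are centred. Chosen after seeing the data were the probe sets of a gene's highest level class, only the 2871 genes with level at least 8, leaving out CD70TG 3 and Ifng-/- 2 together, and median centring of each array within each level class. Bootstrap intervals of list medians are 95% intervals from 10000 resamples of a list's genes. They describe the spread over genes, not over mice. Linkage was tested as genes within 20 Mb of Ifng. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.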

Results

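Gene expression was measured in CD71-enriched bone marrow cells, an enrichment for red cell precursors, from 12 mice of a 2 by 2 design: WT, CD70TG, Ifng-/- and CD70TG*Ifng-/-, with 3 mice and 3 arrays per group. CD70 is the ligand of the T cell costimulatory receptor CD27, and the study asked how chronic CD70 costimulation acts on red cell formation and which part of this needs interferon-gamma. All values are log2 values relative to each gene's median over the 12 arrays. Arrays of the same group differed by a median of 0.085 to 0.138 per gene. On the first principal component, which held 39.3% of the variance, the arrays with the transgene lay between 6.40 and 21.1 and those without it between -24.6 and 3.30. The highest array without the transgene was Ifng-/- 2. Components 2 and 3 held 19.7% and 13.5%, and CD70TG 3 had the highest value on component 3 (20.2).

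The targeted gene, Ifng, did not separate the groups. Its values were 0.027, -0.093 and 0.165 in WT, -0.108, 0.051 and 0.014 in CD70TG, -0.162, -0.014 and -0.025 in Ifng-/-, and -0.109, 0.200 and 0.021 in CD70TG*Ifng-/-. The change was -0.10 ± 0.09 (SE, n = 3 per group, adjusted p = 0.632) in Ifng-/- against WT and 0.05 ± 0.09 (adjusted p = 0.871) in CD70TG*Ifng-/- against CD70TG. Ifng lay in the lower level class, and the labels do not say which part of the gene was removed, so its probe set does not check the labels. Cd70 was 0.26 ± 0.12 higher in CD70TG than in WT (adjusted p = 0.180) and 0.39 ± 0.12 higher in CD70TG*Ifng-/- than in Ifng-/- (adjusted p = 0.135). In both comparisons all 3 transgenic arrays lay above all 3 others, and neither difference passed the threshold. Chance sets 3 arrays apart from 3, in either direction, in 10% of genes. Here 31.1% of all genes were set apart in the first comparison and 16.4% in the second.

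With Ifng intact, the transgene was accompanied by higher expression of interferon-gamma response and MHC class I genes and by lower expression of macrophage, B cell and late red cell maturation genes. With an estimated correlation between genes none of these lists passed (adjusted p = 0.237 for the first 4 and 0.494 for late maturation), and late maturation did not pass without CD70TG 3. Fry passed the first 4 (adjusted p = 0.00164 for MHC class I and 0.00331 for each of the others) and not late maturation (adjusted p = 0.0548). The largest rise among named genes was that of Iigp1, an interferon-inducible GTPase, which was 8.86-fold higher in CD70TG than in WT (3.15 ± 0.24 on the log2 scale, SE, n = 3 per group, adjusted p = 7.17e-06). It was followed by the class I genes H2-Q4 (2.37), H2-Q5 (2.12) and H2-T10 (2.04), the interferon-induced Oasl2 (2.10), Apol10a (1.85), the metal-binding metallothionein Mt2 (1.76), the guanylate-binding proteins Gbp7 (1.66) and Gbp8 (1.64), and the peptide transporter Tap1 (1.65). The largest falls were those of the haem oxygenase Hmox1 (-3.16 ± 0.17, adjusted p = 5.72e-07), the eotaxin receptor Ccr3 (-3.10), and the macrophage genes Mrc1 (-2.93), Vcam1 (-2.78), Cd163 (-2.76), Cd5l (-2.49) and Axl (-2.03), with the transferrin gene Trf (-2.35), Hpgd (-2.34) and Fcna (-2.17).

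Of the 25 measured members of the interferon-gamma response list, 16 rose, 16 also when adjusted over the list alone, and 9 did not pass. The median change was 0.76 (camera, adjusted p = 4.51e-12, and adjusted p = 0.237 with an estimated correlation). Gbp3 rose by 1.57 and the transcription factor Irf1 by 0.77 ± 0.13 (adjusted p = 0.00284). Of 20 MHC class I genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.64 (adjusted p = 4.20e-16, and adjusted p = 0.237 with an estimated correlation), among them the immunoproteasome subunit Psmb9 (1.59). Of 11 MHC class II genes, H2-Ab1 (1.49), H2-Eb1 (1.37) and H2-Aa (1.12) rose and H2-Ob fell (-0.38), with 5 and 2 adjusted over the list alone, and the list did not pass (median 0.28, adjusted p = 0.148). Of 32 type I interferon-stimulated genes, 5 rose and 2 fell (9 and 3 adjusted over the list alone). Zbp1 rose by 1.22, whereas Rsad2 (-0.72) and Isg20 (-0.46) fell, and the list did not pass (median 0.10, adjusted p = 0.0711). The macrophage list, whose cells also carry class II genes, moved the other way over the same arrays.

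Markers of other marrow cells were mostly lower in CD70TG. Of 32 monocyte and macrophage markers, 18 fell and 0 rose (23 fell and 2 rose adjusted over the list alone), with a median of -0.76 (adjusted p = 2.49e-19, and adjusted p = 0.237 with an estimated correlation). They included the complement gene C1qc (-1.88) and Spic (-1.67), a transcription factor of red pulp macrophages. Of 28 B cell markers, 19 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.42 (adjusted p = 1.41e-16, and adjusted p = 0.237 with an estimated correlation), led by the antigen receptor chains Cd79a (-1.53) and Cd79b (-1.31), Bank1 (-0.89) and Vpreb3 (-0.86). Of 24 neutrophil and granule markers, the mature-cell genes Cxcr2 (-1.45), Retnlg (-1.88) and S100a9 (-1.72) fell with 1 other, while 2 rose, among them the early granule gene Prtn3 (1.08). The counts adjusted over the list alone were 16 lower and 5 higher, and the median was -1.10 (adjusted p = 0.0015, and adjusted p = 0.640 with an estimated correlation). Of 16 basophil, mast cell and eosinophil markers, 4 fell, including Ccr3, Prg2 (-2.02) and Ear6 (-1.81), with 5 adjusted over the list alone (median -0.14, adjusted p = 0.00209, and adjusted p = 0.494 with an estimated correlation). Of 16 dendritic cell markers, 4 fell, led by Ly6d (-1.20), with 6 lower and 1 higher adjusted over the list alone (median -0.11, adjusted p = 0.00881, and adjusted p = 0.334 with an estimated correlation). Of 19 stroma and endothelium markers, Vcam1, which the macrophage list also holds, and the Kit ligand Kitl (-0.53) fell, with 2 adjusted over the list alone (median -0.12, adjusted p = 0.00149, and adjusted p = 0.334 with an estimated correlation).

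Of 20 PU.1 and myeloid transcription factors, 4 fell, led by Id2 (-1.10) and Spib (-0.90), with 7 adjusted over the list alone (median -0.27, adjusted p = 9.97e-05, and adjusted p = 0.494 with an estimated correlation). Spi1, which encodes PU.1, was 0.29 ± 0.18 lower in CD70TG, written -0.29 on the log2 scale, and did not pass (adjusted p = 0.353). Plasma cell markers (Jchain, -1.01, fell with 1 other and 1 rose, of 15 members, with 3 and 2 adjusted over the list alone), T cell markers (Cd4, -0.52, fell of 22, 1 adjusted over the list alone), cytotoxic and NK markers (Klrc1, -0.42, fell of 24, 1 adjusted over the list alone) and megakaryocyte markers (F2r, 0.67, rose and Plek, -0.84, fell with 1 other of 15, 1 and 2 adjusted over the list alone) did not pass as lists. Their medians were -0.10, -0.09, -0.07 and -0.11, with adjusted p from 0.0649 to 0.233.

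Among red cell genes, the late maturation list passed as lower in the main setting, and with arrays centred within the level classes the globin and haem and the membrane lists passed as lower too. Of 17 globin and haem genes, 5 fell and 0 rose (5 lower and 3 higher adjusted over the list alone), including Slc25a39 (-0.70), Fech (-0.47) and Alas2 (-0.43), the enzyme that starts haem synthesis in red cell precursors. The list did not pass in the main setting (median -0.07, adjusted p = 0.268) and passed with that centring (median -0.16, adjusted p = 0.00306, and adjusted p = 0.158 with an estimated correlation). Of 20 late maturation and mitophagy genes, 7 fell and 0 rose (7 and 1 adjusted over the list alone), led by the ubiquitin ligase Ube2o (-0.73), the mitophagy receptor Bnip3l (-0.59) and Gabarapl2 (-0.57), with a median of -0.11 (adjusted p = 0.00209, and adjusted p = 0.494 with an estimated correlation). The list did not pass without CD70TG 3 (median -0.04), and its median was -0.20 with centring within the level classes, with 9 lower. Of 24 red cell membrane and surface genes, Bpgm (-0.65) and Trim10 (-0.45) fell and Tfr2 (0.40) rose, with 2 and 1 adjusted over the list alone. That list did not pass in the main setting (median 0.03) and passed as lower with centring within the level classes (median -0.12, 7 fell and 0 rose, adjusted p = 6.61e-05, and adjusted p = 0.17 with an estimated correlation). Of 21 iron genes, 6 fell and 3 rose (8 and 3 adjusted over the list alone). The falls included Hmox1 and the iron exporter Slc40a1 (-1.20), both abundant in macrophages, whose markers fell too, and the ferritin-degradation receptor Ncoa4 (-0.77) and Iscu (-0.79). The list's median was -0.05 (adjusted p = 0.0363, and adjusted p = 0.494 with an estimated correlation), and it did not pass without WT 2, CD70TG 3 or CD70TG*Ifng-/- 2. With centring within the level classes its median was -0.19, with 9 lower and 1 higher (adjusted p = 0.000209, and adjusted p = 0.123 with an estimated correlation).

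Of 21 erythroid transcription factors, Ldb1 (0.40) and Zbtb7a (0.45) rose and 0 fell, with the same counts adjusted over the list alone. The list did not pass (adjusted p = 0.148), and with centring within the level classes its median of 0.17 was 0.00, with 1 gene higher and 5 lower. Gata1 (0.18 ± 0.10, adjusted p = 0.247), Klf1 (0.17 ± 0.09, adjusted p = 0.272), Epor (0.11 ± 0.12, adjusted p = 0.611), Tfrc (-0.02 ± 0.08, adjusted p = 0.902), Socs1 (-0.16 ± 0.12, adjusted p = 0.431) and Cd27 (-0.01 ± 0.10, adjusted p = 0.965) did not pass. Of these, Klf1, Epor and Cd27 had no stable sign across the scalings. Of 19 genes of Epo, Jak2 and Stat5 signalling, Cish (0.40) rose with Stat5b (0.32) and 1 other, and the survival gene Bcl2l1 (-0.50) fell (4 and 1 adjusted over the list alone, list adjusted p = 0.511). Of 22 stem and progenitor genes, Myc (1.25 ± 0.17, adjusted p = 0.000467) and Cdk6 (0.83) rose and 1 fell (2 and 2 adjusted over the list alone, list adjusted p = 0.901).

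All 32 proliferation genes were higher in CD70TG, with a median of 0.20, but 0 passed, also when adjusted over the list alone, and the smallest p was that of Mcm6 (0.27, adjusted p = 0.0565). The list passed (adjusted p = 9.19e-06, and adjusted p = 0.594 with an estimated correlation). All 32 lay in the higher level class, and with arrays centred within the level classes the list's median was 0.03 (adjusted p = 0.567). Of 27 apoptosis genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with the necroptosis effector Mlkl (0.89), Bak1 (0.58) and the death ligand Tnfsf10 (0.55) among the rises (median 0.13, adjusted p = 0.0491, and adjusted p = 0.494 with an estimated correlation). This list did not pass with median centring of each array, nor without WT 1, CD70TG 2, CD70TG 3 or Ifng-/- 2. Of 18 p53 targets, Ccng1 (0.56) rose and Gadd45a (-0.54) fell with 1 other (1 and 2 adjusted over the list alone, list adjusted p = 0.931). Of 21 immediate early and handling stress genes, the chaperones Hsph1 (1.10) and Dnajb1 (0.44) rose and Zfp36 (-0.85) fell with 1 other (2 and 3 adjusted over the list alone, list adjusted p = 0.148). With centring within the level classes that list passed as lower (adjusted p = 0.0297, and adjusted p = 0.632 with an estimated correlation). Of 28 genes flanking Ifng on chromosome 10, 7 rose, led by Cct2 (0.54), and 1 fell (7 and 2 adjusted over the list alone, list adjusted p = 0.137). None of the 5 genes of CD70, CD27 and the interferon-gamma receptor passed, also when adjusted over the list alone (list adjusted p = 0.931).

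In all, 2179 of 19935 genes changed between CD70TG and WT, 1640 higher (75.3%) and 539 lower, against 5237 genes at an unadjusted p under 0.05. At that p 997 genes would be expected by chance. Of the 108 genes changed at least 2-fold, 35 were higher and 73 lower. Brightly measured genes were shifted upwards: the median change of the 2871 genes with a level of at least 8 was 0.19, with 642 called higher and 126 lower, against -0.04 for the other 17064, with 998 called higher and 413 lower. In Ifng-/- against WT the median change of the same 2871 genes was 0.11, so part of the shift lay between WT and other groups. Of the calls, 63.2% were higher after quantile normalization (1590 genes) and 65.0% with centring within the level classes (1778 genes). The number of calls was 853 without WT 1, 1366 without WT 3, 898 without CD70TG 1 and 975 without CD70TG 2, and 3686 with CD70TG 3 and Ifng-/- 2 both left out. Of 79 named genes past the threshold, 63 kept their call without any single array. The others were H2-Eb1, H2-Aa, H2-Ob, Cxcr2, Retnlg, S100a9, Prtn3, Tfr2, Cish, Stat5b, Ccng1, Ldb1, Zbtb7a, Plek, Dnajb1 and Zfp36. Under at least 1 of 3 other scalings the calls of Apol10a, H2-Aa, Tfr2, Ccng1, Ldb1, Zbtb7a and Dnajb1 were lost.

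**Figure D1:**
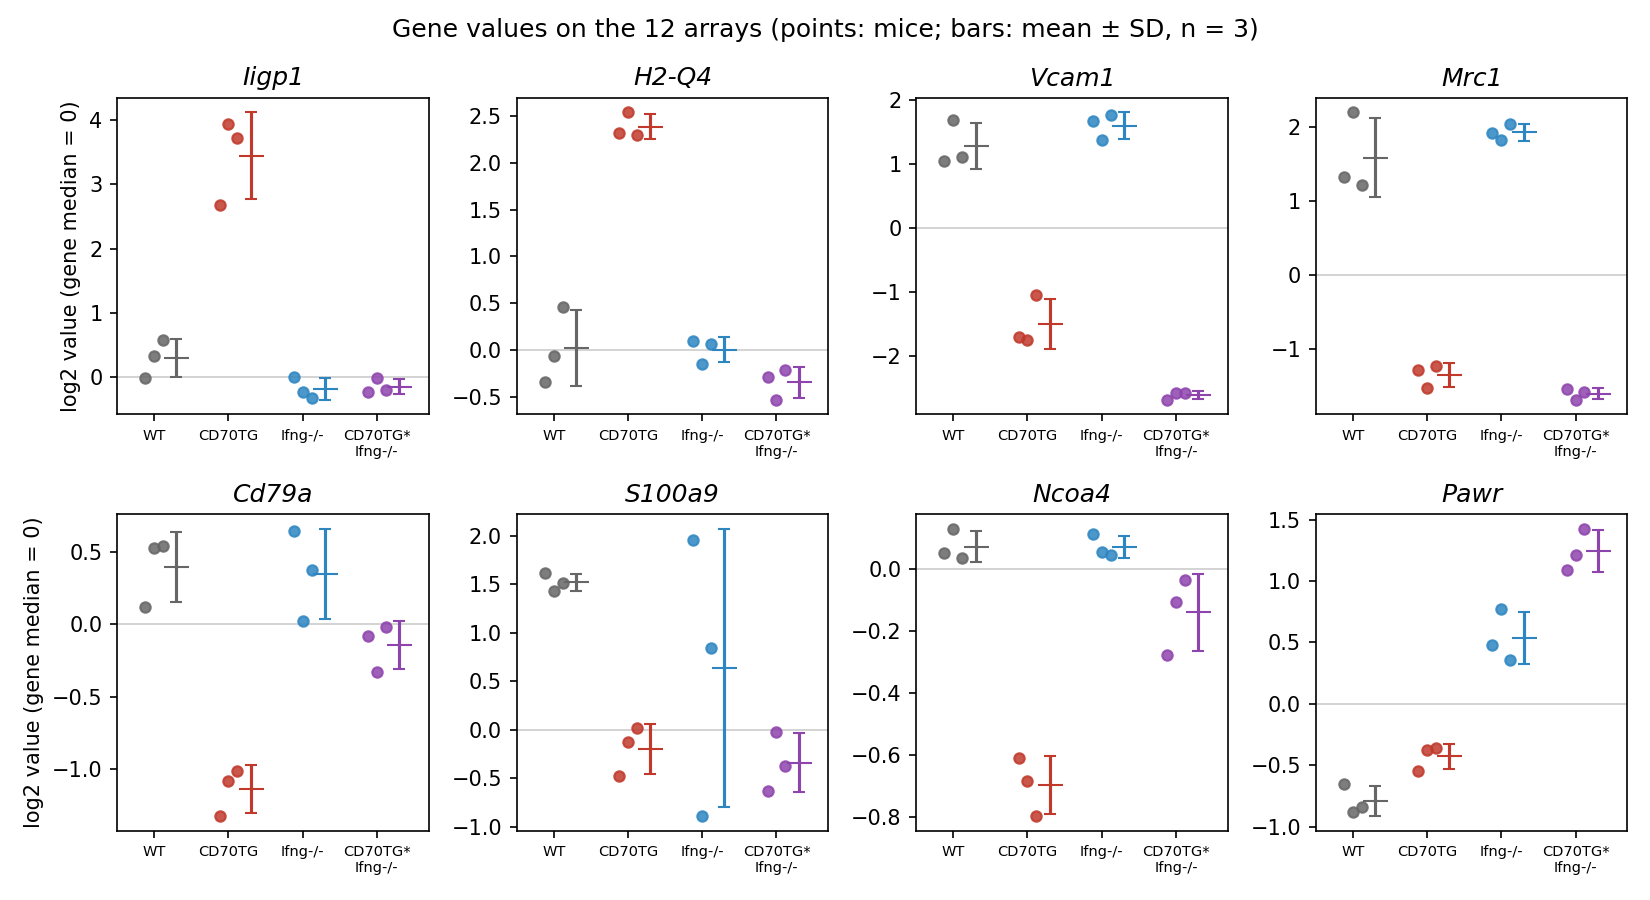
Values of 8 genes on the 12 arrays, as log2 values relative to the gene's median (vertical axes) by group (horizontal axes), with a point per mouse and the mean ± SD of 3 mice beside the points. Iigp1 and H2-Q4 are high in CD70TG alone, Vcam1 and Mrc1 are low in both transgenic groups, Cd79a and Ncoa4 are lowest in CD70TG, S100a9 is spread widely in Ifng-/-, and Pawr is higher in both groups without Ifng.

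Without Ifng, the transgene was accompanied by a fall of macrophage genes and by no rise of interferon response genes. Vcam1, an adhesion molecule of marrow macrophages and stroma, was 18.5-fold lower in CD70TG*Ifng-/- than in Ifng-/- (-4.21 ± 0.18, SE, n = 3 per group, adjusted p = 2.31e-08). Cd5l (-3.72), Hmox1 (-3.68), Mrc1 (-3.53) and Ccr3 (-3.45) followed. The largest rises were small: Snora20 (0.74), Pawr (0.71 ± 0.11, adjusted p = 0.00202), Reln (0.68), Olfr172 (0.64) and Malat1 (0.63).

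Of the 32 monocyte and macrophage markers, 23 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of -1.35 (adjusted p = 7.98e-65, and adjusted p = 0.0424 with an estimated correlation), among them C1qc (-3.12) and Spic (-2.27). Interferon-related genes fell with them. Of 11 MHC class II genes, 5 fell (7 adjusted over the list alone), including the protease Ctss (-2.65), H2-Aa (-1.51), H2-Ab1 (-1.36) and H2-DMa (-0.73), with a median of -0.73 (adjusted p = 1.71e-11, and adjusted p = 0.114 with an estimated correlation). Of 32 type I interferon-stimulated genes, 11 fell (23 adjusted over the list alone), including Rtp4 (-1.49), Lgals3bp (-1.18), Irf7 (-0.98) and Ifit1 (-0.82), with a median of -0.31 (adjusted p = 5.03e-22, and adjusted p = 0.0974 with an estimated correlation). Of 25 interferon-gamma response genes, Gbp8 (-1.04), Casp1 (-0.86) and Irf8 (-0.74) fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.15 (adjusted p = 1.15e-04, and adjusted p = 0.404 with an estimated correlation). Of 20 class I genes only B2m (-0.88) fell, also when adjusted over the list alone (median -0.18, adjusted p = 5.70e-06, and adjusted p = 0.308 with an estimated correlation). Irf1 differed by -0.15 ± 0.13 (adjusted p = 0.689). The receptor chains Ifngr1 (-0.93) and Ifngr2 (-0.79) fell within their list of 5, which did not pass (2 lower and 1 higher adjusted over the list alone, list adjusted p = 0.255).

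Of 28 B cell markers, Bank1 (-0.93) and Cd79b (-0.68) fell (5 adjusted over the list alone, median -0.18, adjusted p = 1.24e-06, and adjusted p = 0.308 with an estimated correlation). No neutrophil marker of 24 passed, with 1 lower when adjusted over the list alone, although all 24 were lower (median -0.75, adjusted p = 1.04e-09, and adjusted p = 0.308 with an estimated correlation). In Ifng-/- the mean of this list was 1.5, -0.56 and 0.37 on the 3 arrays, and the list's median change was -0.13 without Ifng-/- 1 and -1.42 without Ifng-/- 2. The lists of basophils, mast cells and eosinophils (Ccr3 alone of 16, 5 adjusted over the list alone, adjusted p = 8.83e-05), dendritic cells (3 of 16 including Cd83, -0.57, with 5 adjusted over the list alone, adjusted p = 0.00152), PU.1 and myeloid factors (Id2, -1.84, and Irf8 of 20, 5 adjusted over the list alone, adjusted p = 1.41e-06) and immediate early genes (Zfp36, -1.16, Fosb, -0.84, and Fos, -0.84, of 21, 7 adjusted over the list alone, adjusted p = 5.61e-06) passed as lower. With an estimated correlation their adjusted p-values were 0.308, 0.209, 0.308 and 0.209. Spi1 was -0.69 ± 0.18 and did not pass (adjusted p = 0.0782). Cd4 (-1.03), the chemokine Ccl3 (-1.38), Klrc1 (-0.36), Plek (-1.41) and Kitl (-0.45) fell within lists that did not pass.

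Among red cell genes few changed. Slc25a39 (-0.43) was the only one of 17 globin and haem genes to fall, and 0 of 24 membrane genes, 0 of 20 late maturation genes and 0 of 21 erythroid transcription factors passed. The membrane list passed as higher (median 0.11, adjusted p = 0.0182, and adjusted p = 0.675 with an estimated correlation), but not without Ifng-/- 1, Ifng-/- 3 or CD70TG*Ifng-/- 1. Of 21 iron genes, Hmox1, Slc40a1 (-1.09), Hfe (-0.79) and Ftl1 (-0.38) fell (5 adjusted over the list alone, median -0.04, adjusted p = 1.04e-05, and adjusted p = 0.133 with an estimated correlation). Proliferation genes passed as a list with no single gene past the threshold (median 0.13, adjusted p = 0.00152, and adjusted p = 0.675 with an estimated correlation), though not without Ifng-/- 1 (median 0.05). Of 27 apoptosis genes Casp1 fell, with 3 adjusted over the list alone (median -0.13, adjusted p = 9.56e-06, and adjusted p = 0.133 with an estimated correlation).

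In all, 499 genes changed between CD70TG*Ifng-/- and Ifng-/-, 31 higher and 468 lower, and all 159 genes changed at least 2-fold were lower. The number of calls was 320 without Ifng-/- 1, 868 without Ifng-/- 2, 321 without CD70TG*Ifng-/- 2 and 297 without CD70TG*Ifng-/- 3, and 1048 with CD70TG 3 and Ifng-/- 2 both left out. Of 42 named genes past the threshold, 26 kept their call without any single array, and Snora20, Reln, Malat1, Irf8, B2m, H2-Ab1, H2-Aa, Ftl1, Cd79b, Ccl3, Kitl, Zfp36, Fos, Ifngr1, Ifngr2 and Klrc1 did not. Snora20, B2m, H2-Ab1 and H2-Aa also lost their calls under another scaling.

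The pair of transgene effects shared many of their called falls. Shared rises could hardly be judged, since only 31 genes were called higher without Ifng. Across 19935 genes, which are not independent replicates, the fold changes with and without Ifng correlated with r = 0.354 (covariance 0.0196). Over the 2179 genes called with Ifng intact r was 0.684 and the slope of the effect without Ifng on that with it was 0.577, and 1344 of these genes had the same sign in both. Called lower in both were 219 genes, where independent lists would share 12.7 (Fisher's exact test, one-sided p = 7.02e-229). Called higher in both were 4, where 2.55 would be shared (Fisher's exact test, one-sided p = 0.249). Fisher's test takes genes as independent, which they are not, so these p-values describe genes and not mice. The pair of comparisons shares no array.

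**Figure D2:**
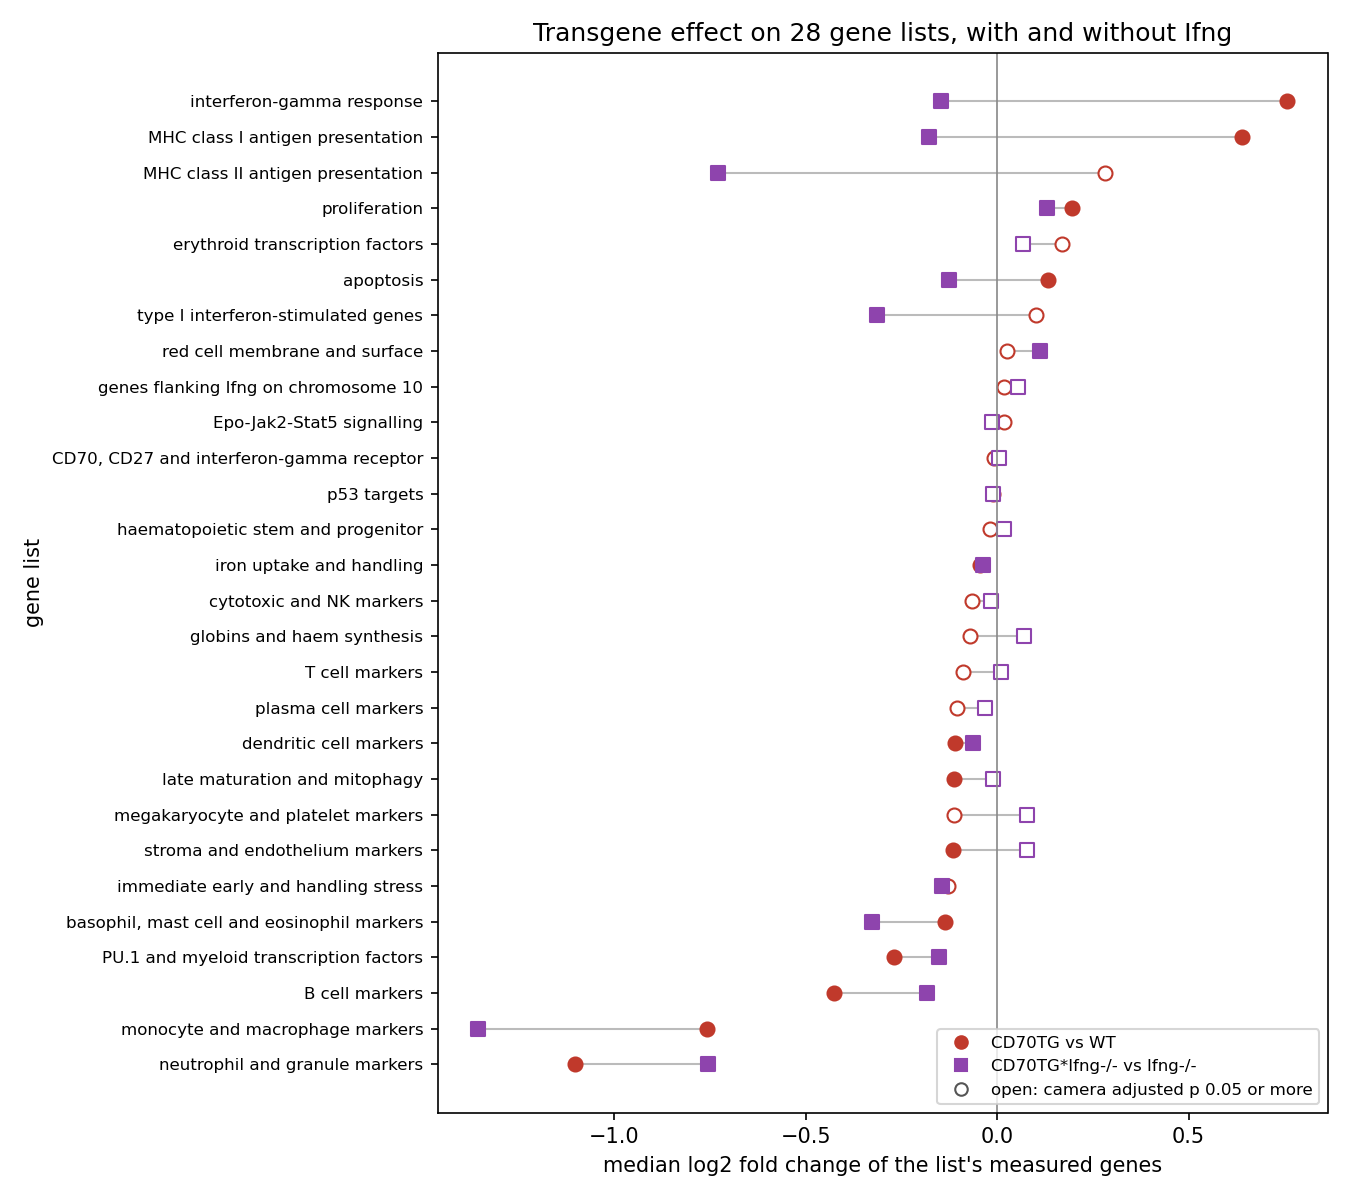
Median log2 fold change (horizontal axis) of each of the 28 gene lists (vertical axis) for the transgene with Ifng intact (red circles) and without Ifng (purple squares), filled where camera's adjusted p with the preset correlation was under 0.05. The interferon-gamma response list lies at 0.76 with Ifng and -0.15 without it, and the macrophage list at -0.76 and -1.35.

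Loss of Ifng without the transgene was accompanied by a single called change. Pawr, a gene on chromosome 10, was 2.50-fold higher in Ifng-/- than in WT (1.32 ± 0.11, SE, n = 3 per group, adjusted p = 0.000215, higher in 3 of 3 mice). Interferon-gamma response genes did not pass: Iigp1 was -0.48 ± 0.24 (adjusted p = 0.381), Cxcl9 -0.36 ± 0.17 (adjusted p = 0.368) and Irf1 -0.10 ± 0.13 (adjusted p = 0.749), and the list's median was -0.04 (adjusted p = 0.709). The heat shock gene Hsph1 was 1.08 ± 0.16 higher and just missed the threshold (adjusted p = 0.0772), with Dnajb1 at 0.48 (adjusted p = 0.217) and Myc at 0.63 (adjusted p = 0.229).

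Of the 28 lists, 3 passed in Ifng-/- against WT, each higher, with no member past the threshold over all genes. They were type I interferon-stimulated genes (median 0.12, adjusted p = 0.000287, led by Oas1a at 0.33), monocyte and macrophage markers (median 0.23, adjusted p = 0.000758, with Csf1r at 0.48 and Adgre1 at 0.67) and immediate early and handling stress genes (median 0.17, adjusted p = 0.000999). Adjusted over the list alone 1, 5 and 6 of their genes rose. For each of them adjusted p = 0.989 with an estimated correlation, and the macrophage median was -0.01 after quantile normalization. Without Ifng-/- 1 none of the 3 passed, with medians of 0.09 for macrophage markers and 0.02 for immediate early genes, and of the 4 lists that then passed 1 was higher and 3 were lower. With centring within the level classes the red cell membrane list passed as lower (median -0.12, adjusted p = 0.000434, and adjusted p = 0.914 with an estimated correlation), against a median of -0.02 in the main setting. In all, 2759 genes, Pawr among them, had an unadjusted p under 0.05, where 997 would be expected by chance. The single call is thus no measure of how few genes differed. The count of 1 was 42 without WT 2, 9 without CD70TG*Ifng-/- 2, 4 without Ifng-/- 2 and 2 without WT 3 or CD70TG*Ifng-/- 1. With CD70TG 3 and Ifng-/- 2 both left out it was 4, with array weights 7, with quantile normalization 5 and over the genes with level at least 8 alone 17. Pawr passed without each of the 12 arrays in turn.

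In transgenic mice, loss of Ifng was accompanied by lower interferon response and antigen presentation genes. Iigp1 was 12.1-fold lower in CD70TG*Ifng-/- than in CD70TG (-3.59 ± 0.24, SE, n = 3 per group, adjusted p = 2.59e-06), followed by H2-Q4 (-2.73), Oasl2 (-2.64) and the class II genes H2-Ab1 (-2.58) and H2-Aa (-2.49). The largest rises were those of Pawr (1.67 ± 0.11, adjusted p = 2.59e-06), the adaptor Grap2 (1.37), the transcriptional co-repressor Runx1t1 (1.26), Chst10 (1.10) and Reln (1.06).

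Of 25 interferon-gamma response genes, 17 fell and 0 rose (18 and 0 adjusted over the list alone), with Gbp8 (-2.39), Gbp7 (-2.04), Gbp3 (-2.03) and Irf1 (-1.01 ± 0.13, adjusted p = 0.000756) among them, and a median of -0.94 (adjusted p = 7.80e-35, and adjusted p = 0.0297 with an estimated correlation). Of 20 class I genes, 14 fell (18 adjusted over the list alone), including Tap1 (-2.04), Psmb9 (-1.98) and Psmb10 (-1.33), with a median of -0.85 (adjusted p = 1.67e-41, and adjusted p = 0.0284 with an estimated correlation). Of 11 class II genes, 6 fell (7 lower and 1 higher adjusted over the list alone), with Ctss (-1.63) and H2-DMa (-0.95), and a median of -0.95 (adjusted p = 6.47e-13, and adjusted p = 0.0884 with an estimated correlation). Of 32 type I interferon-stimulated genes, 10 fell (16 lower and 2 higher adjusted over the list alone), with Rtp4 (-2.01), Zbp1 (-1.25) and Bst2 (-0.56), and a median of -0.26 (adjusted p = 1.87e-15, and adjusted p = 0.0976 with an estimated correlation). Monocyte and macrophage markers fell with these genes: 7 of 32, led by Fcgr4 (-1.73), Ly86 (-1.37), Vcam1 (-1.11) and C1qc (-0.94), with 14 adjusted over the list alone and a median of -0.43 (adjusted p = 1.65e-13, and adjusted p = 0.329 with an estimated correlation), or -0.20 after quantile normalization.

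Of 24 neutrophil and granule markers, the early granule genes Ctsg (-1.58), Mpo (-1.5), Ms4a3 (-1.34) and Prtn3 (-1.29) fell (5 adjusted over the list alone, median -0.14, adjusted p = 0.00447, and adjusted p = 0.870 with an estimated correlation). Mpo was 2.03 on CD70TG 3 against 0.69 and 0.67 on the other CD70TG arrays, and Prtn3 was 1.77 against 0.67 and 0.52. B cell markers moved up: Cd79a (0.99) and Ms4a1 (0.69) rose of 28 (6 adjusted over the list alone, median 0.22, adjusted p = 1.08e-08, and adjusted p = 0.336 with an estimated correlation). Of 27 apoptosis genes, 7 fell (8 lower and 1 higher adjusted over the list alone), including Mlkl (-0.99), Casp1 (-0.94), Tnfsf10 (-0.80) and Casp8 (-0.52), with a median of -0.13 (adjusted p = 2.00e-06, and adjusted p = 0.0976 with an estimated correlation). Stroma markers passed as higher with Vcam1 among the falls (median 0.12, adjusted p = 0.0126, and adjusted p = 0.471 with an estimated correlation), though not without CD70TG 1.

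Late red cell maturation genes passed as a list that was higher in CD70TG*Ifng-/- than in CD70TG. Of 20 late maturation genes Ube2o (0.49) rose, and 8 rose when adjusted over the list alone, with a median of 0.18 (adjusted p = 1.74e-05, and adjusted p = 0.348 with an estimated correlation). Bpgm (0.40) and Trim10 (0.45) rose among 24 membrane genes (2 adjusted over the list alone, median 0.11, adjusted p = 0.00237, and adjusted p = 0.756 with an estimated correlation), and 0 of 17 globin and haem genes rose, 5 when adjusted over the list alone with 1 lower (median 0.11, adjusted p = 0.0425, and adjusted p = 0.665 with an estimated correlation). Neither of these lists passed without CD70TG 3, and the globin and haem list did not pass without Ifng-/- 2, CD70TG*Ifng-/- 1 or CD70TG*Ifng-/- 3 either. The iron genes Ncoa4 (0.56) and Iscu (0.52) rose within a list that did not pass. Myc fell (-0.76 ± 0.17, adjusted p = 0.0349), Jun (0.81) and Gadd45a (0.63) rose, and Ccng1 (-0.59) and F2r (-0.54) fell. Tspan8 (0.54), near Ifng on chromosome 10, rose.

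In all, 282 genes changed between CD70TG*Ifng-/- and CD70TG, 85 higher and 197 lower, and of 64 changed at least 2-fold 5 were higher and 59 lower. The number of calls was 165 without CD70TG 2, 173 without CD70TG 3, 143 without CD70TG*Ifng-/- 2 and 136 without CD70TG*Ifng-/- 3, and 212 with CD70TG 3 and Ifng-/- 2 both left out. Of 47 named genes past the threshold, 32 kept their call without any single array, and Bpgm, Trim10, Myc, Jun, Ctsg, Prtn3, Ms4a3, Mpo, Ms4a1, Casp8, Ube2o, Ccng1, Tspan8, F2r and Bst2 did not. Myc, Ly86, C1qc, Vcam1 and Ms4a1 lost their calls under another scaling.

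The interaction asked which transgene effects differed with and without Ifng. Interferon and antigen presentation genes had the largest differences: the transgene effect was higher with Ifng intact by 3.11 ± 0.34 for Iigp1 (SE, adjusted p = 0.000818), 2.99 for Oasl2, 2.85 for H2-Ab1, 2.72 for H2-Q4 and 2.68 for Gbp8. It was lower with Ifng intact for Grap2 (-1.28 ± 0.21, adjusted p = 0.011), Runx1t1 (-1.22), the B cell gene Cd79a (-1.04), Chst10 (-1.04) and the angiotensin receptor Agtr1a (-1.02).

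The interaction was positive for 16 of 25 interferon-gamma response genes (18 adjusted over the list alone), with Gbp7 at 2.18, Gbp3 at 1.80 and Irf1 at 0.91 ± 0.18 (adjusted p = 0.0265), and a median of 0.91 (adjusted p = 5.97e-16, and adjusted p = 0.194 with an estimated correlation). It was positive for 13 of 20 class I genes (17 adjusted over the list alone), with Tap1 at 1.91, Psmb9 at 1.83 and Psme1 at 1.13, and a median of 0.83 (adjusted p = 1.86e-20, and adjusted p = 0.194 with an estimated correlation). The same held for 6 of 11 class II genes (7 adjusted over the list alone), with H2-Aa at 2.63, Ctss at 2.08 and H2-DMa at 1.03, and a median of 1.03 (adjusted p = 2.69e-07, and adjusted p = 0.209 with an estimated correlation). Among 32 type I interferon-stimulated genes, 11 were positive (20 adjusted over the list alone), with Rtp4 at 2.47 and Lgals3bp at 1.5, and a median of 0.50 (adjusted p = 1.02e-12, and adjusted p = 0.194 with an estimated correlation). Macrophage markers moved with these lists: 8 of 32 were positive (18 adjusted over the list alone), with Fcgr4 at 1.77, Ly86 at 1.64, Vcam1 at 1.43 and C1qc at 1.25, and a median of 0.58 (adjusted p = 2.28e-11, and adjusted p = 0.436 with an estimated correlation). After quantile normalization this median was 0.15.

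B cell markers went the other way, with Cd79a and Vpreb3 (-0.71) negative of 28 (3 adjusted over the list alone), and a median of -0.31 (adjusted p = 3.59e-06, and adjusted p = 0.495 with an estimated correlation). Of 27 apoptosis genes, 4 were positive (10 positive and 1 negative adjusted over the list alone), namely Mlkl (1.13), Casp1 (1.09), Casp8 (0.80) and Tnfsf10 (0.70), with a median of 0.25 (adjusted p = 2.69e-05, and adjusted p = 0.194 with an estimated correlation). Of the red cell genes Bpgm (-0.46) and the iron gene Ncoa4 (-0.56) were negative, and Aco1, the iron-sensing regulator of iron mRNAs, was positive (0.61). The late maturation (median -0.15, adjusted p = 0.0621), membrane (-0.16, adjusted p = 0.107) and globin and haem (-0.17, adjusted p = 0.471) lists did not pass in the main setting. All 3 passed as negative with centring within the level classes (medians -0.28, -0.29 and -0.27, adjusted p = 9.54e-06, 2.85e-07 and 0.00334, and adjusted p = 0.179, 0.179 and 0.183 with an estimated correlation). Myc (1.38 ± 0.23, adjusted p = 0.0119), Hsph1 (1.46) and Ccng1 (0.88) were positive and Gadd45a (-0.79) negative.

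In all, the transgene effect differed with Ifng for 377 genes, 321 positive (85.1%) and 56 negative, against 4041 genes at an unadjusted p under 0.05. At that p 997 genes would be expected by chance. With centring within the level classes 74.2% of 503 genes were positive. The number of calls was 82 without WT 1, 210 without WT 3, 233, 88 and 226 without CD70TG 1, 2 and 3, 180 without Ifng-/- 3, and 711, 85 and 94 without CD70TG*Ifng-/- 1, 2 and 3. It was 175 with CD70TG 3 and Ifng-/- 2 both left out. Of 38 named genes past the threshold, 22 kept their call without any single array, and Irf1, H2-Aa, H2-Eb1, Chst10, Agtr1a, Ly86, Vcam1, Cd79a, Vpreb3, Bpgm, Ncoa4, Aco1, Casp8, Casp1, Tnfsf10 and Ccng1 did not. Under another scaling H2-Aa, Chst10, C1qc, Ly86, Vcam1, Vpreb3, Bpgm and Ncoa4 lost their calls.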

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

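In this part, the tests chosen only after the result was seen are the linkage test of CD70TG*Ifng-/- against CD70TG and the test of the macrophage fall without Ifng. The tests of cell carry-over, of linkage in Ifng-/- against WT, of the B cell fall and of other groupings were planned. Some limits applied to them below, from the level class, olfactory receptor genes and the number of splits, were not part of those plans. By the planned rules alone, the T and NK markers would argue against carry-over. By the same rules the B cell fall would go with fewer cells of every other type.

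The interaction, a test of the difference itself, set apart 377 genes whose transgene effect differed with Ifng. It also gave the list medians of 0.91 for interferon-gamma response, 0.83 for MHC class I, 1.03 for MHC class II, 0.50 for type I interferon-stimulated genes, 0.58 for monocyte and macrophage markers, -0.31 for B cell markers and 0.25 for apoptosis. With an estimated correlation none of these 7 lists passed (adjusted p from 0.194 to 0.495). Fry passed interferon-gamma response (adjusted p = 0.00764), MHC class I (adjusted p = 0.00355), and MHC class II, type I interferon and apoptosis genes (adjusted p = 0.0153 each). It did not pass macrophage (adjusted p = 0.145) or B cell markers (adjusted p = 0.157). By gene it gave 3.11 for Iigp1, 2.99 for Oasl2, 2.85 for H2-Ab1, 2.72 for H2-Q4, 2.68 for Gbp8, -1.28 for Grap2, -1.22 for Runx1t1, -1.04 for Cd79a, -1.04 for Chst10 and -1.02 for Agtr1a. Of 100 regroupings of the 12 arrays, 1, the real one, gave as many genes, and the highest of the others gave 16. Regrouping all 12 arrays also breaks up the transgene effect itself. The regroupings thus speak against no group difference at all, and cannot exclude chance for the interaction alone. The 3 against 3 comparisons allow 10 splits, too few for a share under 0.05: the real split gave 2179, 499, 1 and 282 genes for CD70TG against WT, CD70TG*Ifng-/- against Ifng-/-, Ifng-/- against WT and CD70TG*Ifng-/- against CD70TG, and the highest other split gave 0 in each. Outside the named genes, 214 probe sets with several symbols or none were higher in CD70TG than in WT. They belong to no comparison of genes here, and 143 others were lower.

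The rise of interferon-gamma response genes in CD70TG (list median 0.76, bootstrap interval 0.05 to 1.15) could come from myeloid or T and NK cells carried through the enrichment, since these cells express many of the same genes. The tables argue against more monocytes and macrophages as the whole account, since their markers had a median of -0.759 (interval -1.25 to -0.51) where carry-over needs them higher. More immature granule-forming cells were not tested. Of 24 neutrophil and granule markers 4 fell and 2 rose, among the rises the early granule gene Prtn3. More T or NK cells cannot be told apart: their markers were not higher, with a median of -0.078 (interval -0.10 to -0.04), but all lay in the lower level class and moved like olfactory receptor genes (-0.07), so a small share of cells would not be seen. A response inside the red cell precursors and one inside a changed set of remaining other cells stay open.

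Macrophage and B cell markers were lower with the transgene, and fewer cells of every other type is a candidate explanation. For the B cell fall in CD70TG against WT it cannot be told apart from separate changes of some cell types: the medians of the 5 lists tested, B cells and 4 others, were all negative, but the T cell (interval -0.11 to -0.03) and megakaryocyte (-0.20 to -0.05) intervals hold the median of olfactory receptor genes (-0.07), so their sign decides nothing. For the larger macrophage fall without Ifng this explanation cannot be told apart either. Between the transgene effects with and without Ifng the upper end of the B cell interval was -0.225 and the macrophage interval ran from 0.42 to 0.75. These intervals cover genes, not mice. With an estimated correlation neither list passed in the interaction (camera, adjusted p = 0.436 for macrophage and 0.495 for B cell markers). After quantile normalization the macrophage median was 0.15 in place of 0.58, and its interval (0.05 to 0.32) still lay apart from that of B cells (-0.39 to -0.21). A specific change of macrophages, in number or in expression, stays open and was not tested on cell counts.

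Pawr was the 1 gene changed in Ifng-/- against WT. A gene targeted in cells of another strain can carry linked variants, so linkage on chromosome 10 may account for it: 1 of 1 changed gene lay within 20 Mb of Ifng, as do 1.3% of genes (Fisher's exact test, one-sided p = 0.013). Of the 282 genes of CD70TG*Ifng-/- against CD70TG, 2, Pawr and Tspan8, lay near where 3.66 would by chance (Fisher's exact test, one-sided p = 0.884). This argues against linkage as an account of these genes as a set, and leaves it open for Pawr and Tspan8. Pawr was also higher with the transgene in mice without Ifng (0.71), which linkage alone does not give, and the strain of the targeted cells is not given in the sources used here.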

How the results depend on the processing

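Chosen after seeing the data were the highest level class of probe sets, genes with level at least 8 only, leaving out CD70TG 3 and Ifng-/- 2 together, and centring within the level classes. All others were planned. Not run, since centred values hold no level, were the highest-mean probe set and both filters on the dimmest genes. Of 233 results of named genes 227 never reversed, as did 49 of the 50 results of lists that passed in the main setting. Medians of lists that did not pass could turn in sign. That of red cell membrane genes in CD70TG against WT went from 0.025 to -0.122 with level-class centring. Of 207 called genes, 207 never reversed and 129 kept their call in all settings followed gene by gene. The stricter thresholds and every probe set were not followed gene by gene. The setting with level at least 8 covered only genes of that class.

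The 2179 genes of CD70TG against WT became 5337 with array weights, 108 at 2-fold, 673 at an adjusted p of 0.01, 1166 with level at least 8 and 3686 without CD70TG 3 and Ifng-/- 2. Without single arrays they ranged from 853 (WT 1) to 2721 (Ifng-/- 2). Quantile normalization gave 1590 (1485 shared) and level-class centring 1778 (1568 shared). The 499 of CD70TG*Ifng-/- against Ifng-/- became 1439, 159, 277, 64 and 1048 in the first 5 settings, and 297 (CD70TG*Ifng-/- 3) to 868 (Ifng-/- 2) without single arrays. The 1 of Ifng-/- against WT became 2 with only the arrays compared, 5 with quantile normalization, 4 with every probe set, 2 with a trend and robust prior, 7 with array weights, 17 with level at least 8, 4 without CD70TG 3 and Ifng-/- 2, and 1 to 42 (WT 2) without single arrays. The 282 of CD70TG*Ifng-/- against CD70TG became 3519 with array weights, 64 at 2-fold, 132 at 0.01, 151 with level at least 8, and 136 (CD70TG*Ifng-/- 3) to 365 (CD70TG*Ifng-/- 1) without single arrays. The 377 of the interaction became 2040 with array weights, 89 at 2-fold, 52 at 0.01, 175 without CD70TG 3 and Ifng-/- 2, and 82 (WT 1) to 711 (CD70TG*Ifng-/- 1) without single arrays. The cause was not tested.

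With the replicate number as a block the counts were 1668, 401, 1, 214 and 128. The numbers do not pair the arrays: of 18 same-numbered pairs the correlations ran from -0.33 to 0.30, 2 were over 0.1, and 1 of 12 arrays correlated best with its own number.

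Lists past the threshold, 13, 15, 3, 12 and 7 in the order above, became 0, 1, 0, 2 and 0 with an estimated correlation. Fry gave 8 in CD70TG against WT, 4 in CD70TG*Ifng-/- against Ifng-/-, 0 in Ifng-/- against WT and 5 in CD70TG*Ifng-/- against CD70TG. In the interaction it passed the interferon-gamma response, MHC class I, MHC class II, type I interferon and apoptosis lists. With level at least 8, where 13 lists in place of 28 could be tested, the first 2 were 8 and 6, and without CD70TG 3 and Ifng-/- 2 Ifng-/- against WT had 7. Without single arrays they ranged from 12 to 15, 13 to 19, 3 to 7, 11 to 12 and 7 to 11. The correlation of the transgene effects, 0.354, was 0.684 over called genes and 0.240 to 0.463 without single arrays.

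Signs reversed for Cd27 in CD70TG against WT with quantile normalization (0.002) and level-class centring (0.013), and from -0.083 to 0.037 without single arrays. In the same comparison Klf1 (0.000) and Epor (-0.064) reversed with level-class centring, Tfrc reversed with array weights (0.042) and without CD70TG 3 and Ifng-/- 2 (0.053), and ranged from -0.061 to 0.053 without single arrays, and Ifng ranged from -0.111 to 0.018. In CD70TG*Ifng-/- against CD70TG, Ifng reversed with array weights (-0.002) and ranged from -0.030 to 0.125. The macrophage list in Ifng-/- against WT reversed with quantile normalization (-0.013).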

Other observations

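In this part, the tests of the macrophage split, of late-stage red cell genes and of the chaperone, proteasome and ribosomal lists were chosen only after the result was seen.

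The macrophage fall was uneven over the list. The 13 genes of resident marrow macrophages, among them Vcam1, Cd163 and Mrc1, had a median of -1.66 in CD70TG against WT and the 19 other genes of the list -0.51, a difference of -1.15 (permutation over genes, two-sided p = 0.00105). Without Ifng these were -2.66 and -1.16 (difference -1.50, permutation p = 0.00606). This split was drawn up after these falls were seen, so the p-values decide nothing between a loss of resident macrophages and one of all monocytic cells. A count of these cells by surface staining in all 4 groups would be a test.

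In CD70TG 7 of 20 late maturation genes fell, and fewer late-stage red cell precursors may underlie this. The list did not pass with an estimated correlation (adjusted p = 0.494), nor without CD70TG 3 (median -0.04). This cannot be told apart from a lower expression of these genes in the same cells. After centring within the level classes the membrane list had an interval of -0.27 to -0.07 (upper end -0.068), which such a loss needs, but that of globin and haem genes, -0.31 to 0.04, crossed 0. The result rests on the centring: before it the membrane median was 0.03 and after it -0.12. The brightness shift itself has no known origin here. The medians of bright genes were -0.14, -0.06 and -0.12 in WT and 0.14, 0.08 and -0.03 in CD70TG. They were -0.08, 0.11 and -0.03 in Ifng-/-, and 0.08, -0.01 and 0.03 in CD70TG*Ifng-/-. The median change of bright genes was 0.11 in Ifng-/- against WT and 0.04 in CD70TG*Ifng-/- against Ifng-/-, so the shift is not particular to the transgene.

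Chaperone and proteasome genes were also higher in CD70TG. Of 15 heat shock genes 13 rose (median 0.50), of 45 proteasome genes outside the class I list 24 rose and 1 fell (0.31), of 77 mitochondrial ribosomal genes 26 rose (0.27) and of 57 cytosolic ribosomal genes 12 rose (0.17). Centred within the level classes these medians were 0.33, 0.16, 0.24 and 0.01, with 8, 9, 19 and 4 genes higher, so the cytosolic ribosomal rise depends on the scaling. With an estimated correlation adjusted p = 0.128 for heat shock, 0.143 for the proteasome and 0.154 for mitochondrial ribosomes. Hsph1 was lowest in WT (-1.20, -0.78 and -0.94), with CD70TG*Ifng-/- 2 close to it (-0.69) and the remaining arrays no lower than -0.11. Most of the difference thus lay between WT and the rest. The heat shock list was likewise higher in Ifng-/- than in WT (median 0.47, adjusted p = 0.0469 with an estimated correlation, 0 genes past the threshold) and had a median of -0.07 in CD70TG*Ifng-/- against Ifng-/-, so its rise is not particular to the transgene.

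The class II gene H2-Ab1 rose with the transgene where Ifng was intact (1.49) and fell where it was missing (-1.36, a call lost without some single arrays), with an interaction of 2.85. The class II list did not pass with Ifng intact (adjusted p = 0.148), and its fall without Ifng had adjusted p = 0.114 with an estimated correlation. Ccr3, a receptor of eosinophils, was lower in both transgenic groups, as macrophage genes were. On the Ifng-/- arrays Ccr3 was 1.96, 1.79 and 1.99, and Prg2 was 1.78, -0.12 and 1.45. Spi1, the gene of PU.1, was not higher in CD70TG (-0.29, adjusted p = 0.353). Macrophage markers fell in the same comparison (median -0.76), so this value does not give the level of Spi1 in red cell precursors alone. Grap2, Runx1t1, Chst10 and Agtr1a were lower with the transgene only where Ifng was intact, with interactions of -1.28, -1.22, -1.04 and -1.02.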
